A study of Zea mays with 2 samples.

How the data were processed

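The series comprises 1 MNase library and 1 input library from flowers of the maize inbred line B73. Per the labels' protocols, nuclei were sonicated for 5 s and digested with 0.02 U/µl micrococcal nuclease for 10 min, fragments near 150 bp were cut from a 2% agarose gel, and about 100 ng of that DNA went into the Illumina library. The control was chromatin sheared to 200 to 500 bp, per the labels' protocols. CASAVA 1.8 and BWA are named in the submitters' processing notes, without their role or order. The genome build, the peak caller, the reads it was run on, and any filter on mapping quality or duplicates are not given in the sources used here.

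The data used were 1 table of regions, with chromosome, start, end, length and a ratio in each of 3126 rows and no header. The length was end minus start in all 3126 rows, so positions were read as counted from 0 and are printed from 1. The values used were the length and the ratio. The length, deposited by the authors in bp, belongs to no library. The ratio is a linear ratio that the authors deposited with 1 value per region. The table also holds 2 columns of whole numbers that were not used as measurements. Neither carries a name, so neither could be matched to the MNase or the input library, and no measurement was taken from them. They were read only to find how the ratio had been formed. In 3126 of 3126 rows the deposited ratio equalled 0.176 times the first of them divided by the second plus 1, within a tolerance of 1e-05. What the constant 0.176 stands for is not given in the sources used here. Adding 1 to the denominator keeps a ratio finite where the denominator is 0, and lowers ratios most where the denominator is small. The ratio is thus least precise in regions with few reads, and depth per region was not used here.

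The comparisons were fixed before the data were examined, but for read counts of both libraries. As these could not be named, the unit was changed to the deposited ratio and the statistic from log2 ratios with a pseudocount to medians and ranks that include regions at 0. The planned per-region exact binomial tests, the planned minimum of reads and the planned pseudocounts need named counts and were not run. Planned comparisons with genes, gene parts and GC content need a genome of the same build and were not run either, so the fixed gene lists (meiotic recombination and chromosome axis, chromatin and DNA methylation, anther and tapetum development, housekeeping) gave no result. The rule for named regions took the 10 highest and the 10 lowest ratios among all regions; the lowest could not be ranked because of ties at 0, and the regions with most input reads could not be chosen without named counts.

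Regions of 1 genome are not independent replicates, so the 10 numbered chromosomes served as units in tests of position and length. The distance to the chromosome end was taken from position 0 and from the end of the last listed region, which stands in for the unknown chromosome length. Distal regions had their midpoint within 20% of this span from an end. Distal and proximal medians were compared per chromosome as a log2 difference, and ratio and length by Spearman's rho per chromosome. Both were tested by an exact two-sided sign-flip permutation test over all 1024 sign patterns, whose smallest p is 0.00195. Medians were taken with regions at 0 included, so no pseudocount was needed. Medians per chromosome were planned without a test. Further tests were added after the data had been seen: shuffling for the range of chromosome medians and for the ratios of adjacent regions (100000 shuffles each, for adjacent regions within chromosomes), the number of close pairs (10000 random placements), the share of regions near the ends, the relation to the distance from the end and the mean ratio by length. With the planned tests these make 12, over which Benjamini-Hochberg adjusted p-values are given; the follow-up tests by gap class are given unadjusted. They describe the spread between regions or chromosomes of this single pair of libraries and not between plants.

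The tests were checked on simulated data at the real positions and lengths of the 3120 regions. Without an effect, 5% of 200 runs were called for the distal comparison, 6% of 200 for length and 5.25% of 400 for adjacent pairs (500 shuffles per run). With a distal log2 difference of -0.2, the same on every chromosome, 99.5% of runs were called and the mean estimate was -0.20. With a ratio that grew as length to the power 0.3, 100% of runs were called, and with a factor shared by neighbours (log SD 0.6), 98.75%. The sizes of these simulated effects were not matched to the observed relations. The rates therefore do not tell how often effects of the observed size would be called. Alternatives left out regions at 0, the shortest and longest 10% of regions or each chromosome in turn, and set the distal limit to 10% or 30%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.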

Results

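Nucleosome occupancy was assayed in flowers of the maize inbred line B73, the line that also gave the species its reference genome. In MNase-Seq, micrococcal nuclease digests the DNA between nucleosomes and the protected fragments are sequenced. The series holds 1 MNase library, made from fragments of about 150 bp, and 1 input library, made from chromatin sheared to 200 to 500 bp. Neither library has a replicate. The series title concerns meiotic double-strand break hotspots, the sites at which meiotic recombination starts, and its design sets MNase reads against meiotic input. The authors' deposited table gives 1 count ratio for each of 3126 regions. The table has no header, so it does not say which library is the numerator. Ratios are therefore described below as higher or lower and not as more or less nucleosome occupancy. The whole numbers from which the ratio was formed carry no name and were not used as measurements, so no counting interval is given for a single region.

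The listed regions lay on all 10 numbered maize chromosomes and were short and widely spaced. Of the 3126 regions, 3120 were on chromosomes 1 to 10 and 6 carried the chromosome label 0. Their lengths ran from 800 to 3928 bp with a median of 1105.5 bp and quartiles of 910 and 1463.75 bp, and together they covered 3.81 Mb. Lengths were crowded at the lower end, with 734 regions (23.5%) of 900 bp or less and none under 800 bp. No regions overlapped or touched, and the median gap between neighbours was 449 kb. Chromosome 1 carried 418 regions, the highest number, and chromosome 10 carried 237, the lowest. Relative to the last listed position of each chromosome, the density ran from 13.8 regions per 10 Mb on chromosome 8 to 16.7 on chromosome 4. The widest gap without a listed region was 6.20 Mb, on chromosome 1 between positions 28424461 and 34621569. The genome build is not given in the sources used here, so positions are those of the deposited table and no gene was assigned to a region.

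Regions were spread along the chromosomes, and no preference for their ends or interiors was detected. On average 39.4% ± 3.20 (SD, n = 10 chromosomes) of a chromosome's regions lay in the outer 20% at either end, where an even spread would put 40%. The share ran from 35.5% on chromosome 8 to 44.8% on chromosome 7. No difference from an even spread was detected (exact two-sided sign-flip permutation test over chromosomes, p = 0.594, adjusted p = 0.648). In steps of 10% from the end to the middle, the classes held 605, 614, 639, 644 and 618 regions.

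At a finer scale, more adjacent regions lay less than 10 kb apart than random placement would give. Such close pairs took in 153 of the 3120 regions on numbered chromosomes. In all, 77 adjacent pairs were separated by less than 10 kb, against 47.1 (95% range 34 to 61) in 10000 uniform placements on the same chromosomes, a ratio of 1.64. In a one-sided permutation test by random placement p was 1e-04, the smallest that this number of placements can give (adjusted p = 0.0012). Gaps of 5 to 10 kb accounted for 46 of the pairs, against 24.1 in placements that kept the number of regions in every 5 Mb window, a ratio of 1.91 (95% counting interval 1.40 to 2.55). Gaps under 5 kb gave 31 pairs against 24.4 in the same placements, a ratio of 1.27 (0.864 to 1.80), which did not pass the threshold (one-sided permutation test by placement, p = 0.108). Pairs 5 to 10 kb apart occurred on all 10 chromosomes. This comparison, with its gap classes, was chosen after the positions had been seen.

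**Figure D1:**
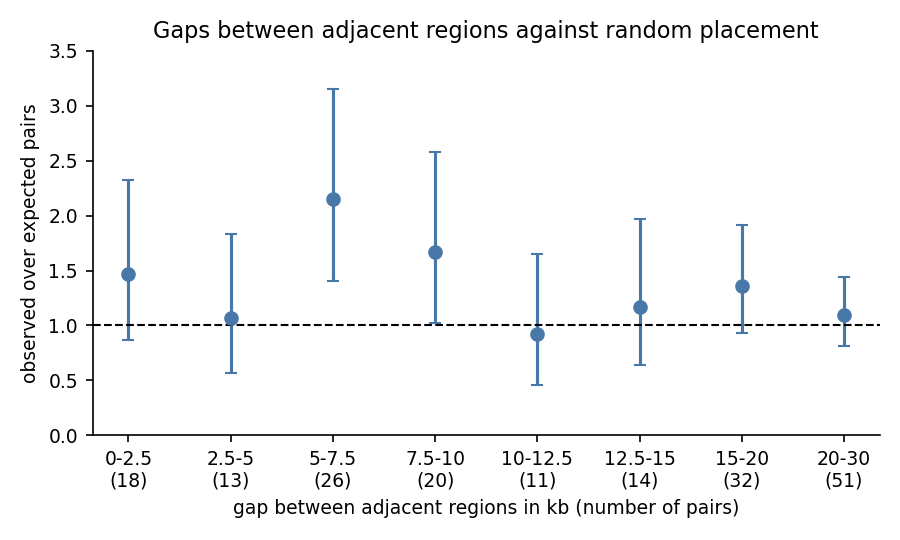
Number of adjacent region pairs (y axis, observed over expected from random placement within 5 Mb windows) by the gap between the regions in kb (x axis, with the number of pairs in brackets). Points are ratios, bars are 95% Poisson counting intervals and the dashed line marks 1; the interval of gaps from 5 to 7.5 kb runs from 1.41 to 3.15 around a ratio of 2.15.

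The design compares MNase with input, and the deposited ratio is the value through which that comparison could be described, although the file does not name its terms. Over the 3126 regions its median was 0.838 (95% order-statistic interval 0.823 to 0.860, over regions), with quartiles of 0.588 and 1.16 and a mean of 0.917. The ratio was below 1 in 2016 regions (64.5%) and above 1 in 1110. Taken as reciprocals, with regions at 0 counted as above 1, these shares change places. As deposited, 123 regions (3.93%) had a ratio above 2 and 21 above 3. On the other side 540 regions (17.3%) were below 0.5, including the 138 at 0, which have no reciprocal. The reciprocals of the others would lie above 2, but exchanging the terms of the ratio would also move the added 1. The ratio had been multiplied by a constant that the file does not explain, so a value of 1 cannot be read as equal occupancy of both libraries. With 1 library of each kind there is no replicate check and no test between MNase and input. The values were coarse, since the 3126 regions took 884 distinct values and the most frequent one above 0, 0.705, was shared by 72 regions.

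**Figure D2:**
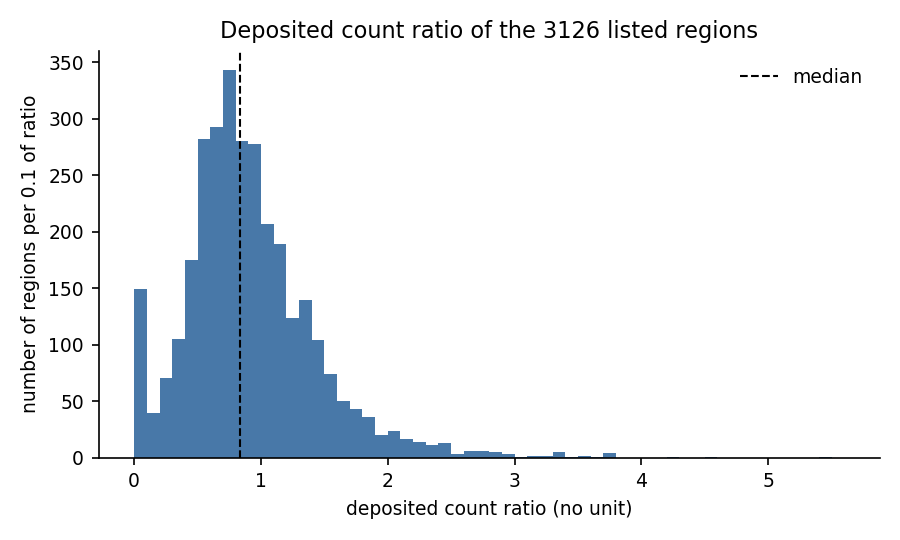
Number of regions (y axis) in classes of 0.1 of the deposited count ratio (x axis, no unit) for all 3126 listed regions. The dashed line is the median, 0.838. The bar at the left holds the 138 regions listed at 0 together with ratios above 0 and below 0.1, the lowest of which was 0.0353. The tail reaches 5.47.

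The highest deposited ratios belonged to single regions on several chromosomes, and their order is not firm, because the precision of each ratio was not assessed here. If the numerator is the input, the same regions would lie toward the low end of a ratio of MNase to input. Where the regions at 0 would then lie depends on whole numbers that were not used here. The region with the highest ratio in the authors' deposited table, 5.47, lay on chromosome 5 from 27061233 to 27062084. Next in the authors' deposited table were regions on chromosome 4, from 67649628 to 67650565 with a ratio of 4.58 and from 101816668 to 101818268 with a ratio of 4.28. A region on chromosome 1 from 156942174 to 156942974 followed in the authors' deposited table with 3.79, and 1 on chromosome 6 from 107178105 to 107179876 with 3.77. The remaining 5 of the 10 highest lay between 3.53 and 3.70 in the authors' deposited table, on chromosomes 1, 2, 4, 5 and 8. The 10 regions came from 6 chromosomes, and 6 of them were shorter than the median region. Of these 10 ratios, 6 were whole multiples of the constant in the ratio, 0.176, against 475 of the 2988 regions above 0 (15.9%), within 0.001 of a whole number. Whole multiples are what the lowest possible denominator gives, although larger denominators can give them too, so the ranking may rest on the least precise regions.

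At the other extreme, 138 regions (4.41%) were listed at 0 in the authors' deposited table. Because so many regions tied there, no 10 lowest regions could be named. All 6 regions of chromosome 0 were at 0, against 132 of the 3120 regions (4.23%) on the numbered chromosomes. Among the numbered chromosomes the share at 0 ran from 2.15% on chromosome 1 to 6.58% on chromosome 9. The lowest ratio above 0 was 0.0353.

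Chromosomes resembled each other in their ratios. Chromosome medians ran from 0.780 on chromosome 6 to 0.876 on chromosome 7, a range of 0.0967, and the quartiles of all 10 chromosomes overlapped. Shuffling the ratios over the regions gave a median range of 0.0937 and a range at least as wide as the observed one with p = 0.459 (permutation test, 100000 shuffles, adjusted p = 0.551). No difference between chromosomes beyond the spread of regions was detected.

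Position along the chromosome was compared because maize chromosome ends and interiors differ in gene content and recombination. The 1219 regions within 20% of a chromosome end had a median ratio of 0.823 (quartiles 0.567 and 1.12), and the 1901 other regions had 0.856 (0.602 and 1.19). The distal median was lower on 7 of 10 chromosomes, with a mean log2 difference (distal minus proximal) of -0.08 ± 0.15 (SD, n = 10 chromosomes). The difference did not pass the threshold (exact two-sided sign-flip permutation test, p = 0.117, adjusted p = 0.277). Single chromosomes differed in sign, from a log2 difference of -0.26 on chromosome 10, where the medians were 0.770 and 0.921, to 0.13 on chromosome 8, where they were 0.885 and 0.807. Spearman's rho between the ratio and the distance to the nearer end averaged 0.06 ± 0.09 (SD, n = 10 chromosomes) and was positive on 6 chromosomes (exact two-sided sign-flip permutation test, p = 0.0625, adjusted p = 0.188). On simulated ratios at the same positions, a log2 difference of -0.2 was called in 99.5% of 200 runs. That simulated difference was the same on every chromosome and larger than the observed mean of -0.08. How often a difference of the observed size and spread would be called was not simulated.

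**Figure D3:**
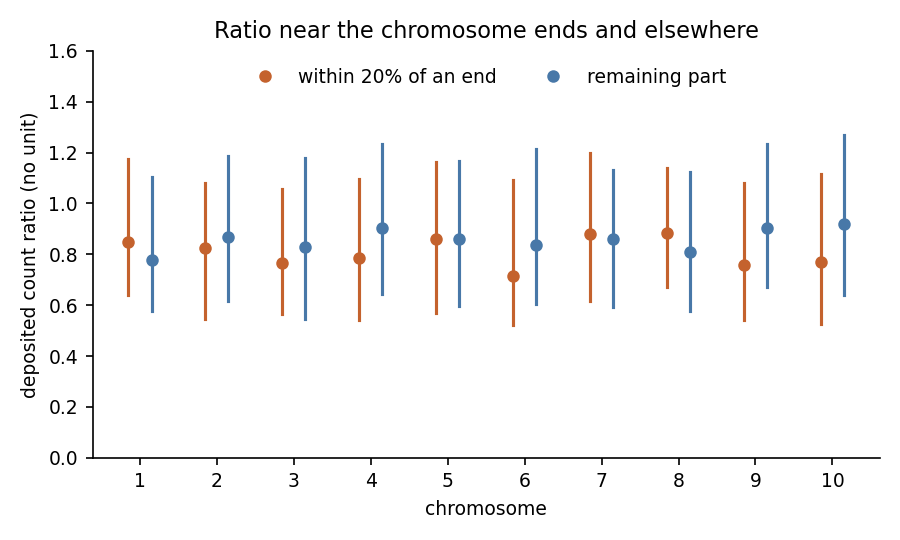
Deposited count ratio (y axis, no unit) by chromosome (x axis) for regions within 20% of a chromosome end and for the remaining regions. Points are medians over regions and bars run from the lower to the upper quartile; distal medians are lower on 7 of the 10 chromosomes and the bars overlap on all of them.

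Longer regions had slightly higher median ratios. Regions longer than the median of 1106 bp on the numbered chromosomes had a median ratio of 0.882, and the shorter ones had 0.799. Over length classes the median rose from 0.793 at 800 to 900 bp (731 regions) to 0.926 above 2000 bp (119 regions). Spearman's rho between length and ratio was positive on 10 of 10 chromosomes, with a mean of 0.08 ± 0.07 (SD, n = 10 chromosomes) and a range from 0.00104 to 0.177. The exact two-sided sign-flip permutation test gave p = 0.00195, the smallest that 10 chromosomes allow (adjusted p = 0.0117 over 12 tests). Over all 3120 regions rho was 0.0856, a weak relation across regions, which are not independent replicates. The lower quartile rose from 0.529 in the shortest class to 0.758 in the longest, while the upper quartile was 1.15 and 1.16. The 95th percentile was lower in the longest class, 1.65 against 1.94 in the shortest, with 1.92 at 1201 to 1500 bp. High ratios thus did not rise with length as the median did. The share of regions at 0 was 6.57% in the shortest class and 1.68% in the longest. In mean ratio, longer and shorter regions differed by 0.0397 ± 0.0790 (longer minus shorter, SD, n = 10 chromosomes), which did not pass the threshold (exact two-sided sign-flip permutation test, p = 0.139, adjusted p = 0.277). The 1 added to the denominator of every ratio lowers it most where the denominator is small.

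**Figure D4:**
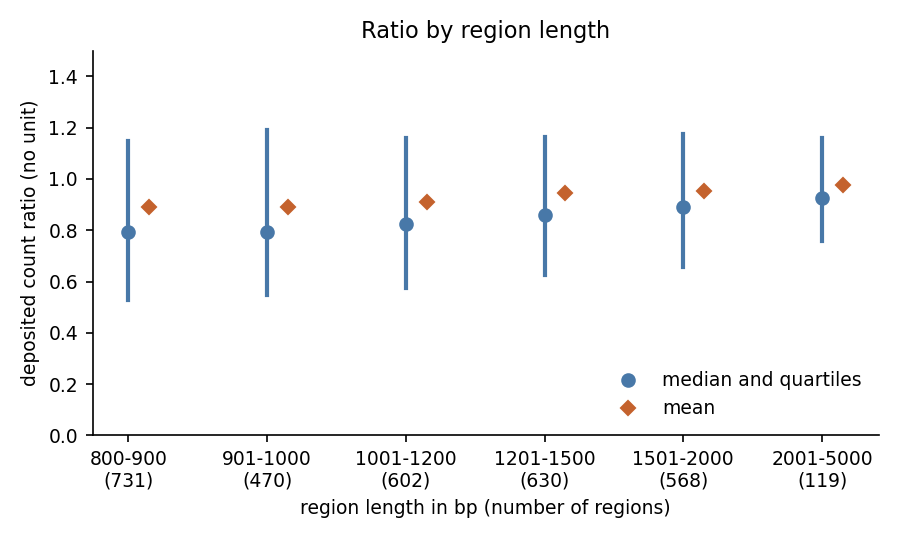
Deposited count ratio (y axis, no unit) by class of region length in bp (x axis, with the number of regions in brackets). Circles are medians, bars run from the lower to the upper quartile and diamonds are means; the median goes from 0.793 to 0.926 and the upper quartile stays between 1.15 and 1.19.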

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

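The rise of the ratio with length stayed past the unadjusted threshold in all 12 alternatives, with a mean rho from 0.0655 to 0.0905. In 10 of them 1 chromosome was left out, and the exact sign-flip permutation test gave p = 0.00391 each time. That p was bound to follow from a positive rho on all 10 chromosomes. By the same test, p was 0.00586 without regions at 0 and 0.0156 without the shortest and longest regions. The distal difference stayed short of the threshold in all 15 alternatives, from -0.11 to -0.03 on the log2 scale. The share of regions below 1 stayed between 62.9% and 64.9%. The share near the ends departed from an even spread by -1.17 to -0.136 percentage points over 12 alternatives. None of these departures passed the threshold (exact two-sided sign-flip permutation test, p at least 0.25). Leaving out the regions at 0 raised the median ratio to 0.862, just above its interval, which follows from removing the lowest values. It also narrowed the range of chromosome medians to 0.0735, whereas leaving out the shortest and longest regions widened that range to 0.127. The cause of neither change in range was tested. Pairs under 5 kb apart exceeded uniform placement 1.31 times (one-sided permutation test by placement, p = 0.0855), short of the threshold; the 20 kb limit passed it (1.44 times, p = 1e-04), as did the 10 kb limit without each chromosome in turn (1.59 to 1.70 times, p at most 0.0004). The similarity of neighbours under 10 kb apart (rho 0.227) lost its unadjusted call at gaps under 5 kb (0.175), under 20 kb (0.0899), without regions at 0 (0.211) and without the shortest and longest regions (0.174); without single chromosomes it ran from 0.165 (without chromosome 10) to 0.322 (without chromosome 7), with p from 0.00701 to 0.174, and without chromosome 1, 3 or 4 p lay too near 0.05 to count as kept or lost. Merging regions changed nothing, since none touched. Alternatives that need named read counts or a genome were not run. No paired analysis was possible because each group holds 1 library.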

Other observations

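The tests of explanations in this part were written down before their own results were seen, but all of the patterns they address, apart from the planned relation to length, were found in the same data.

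Ratios of neighbouring regions were nearly unrelated. Spearman's rho between adjacent regions was -0.02 over 417 pairs 10 to 100 kb apart, 0.03 over 677 pairs 100 to 300 kb apart, 0.03 over 1243 pairs 300 to 1000 kb apart and 0.04 over 696 pairs farther apart (permutation p from 0.269 to 0.688). No correlation past the threshold was detected at these distances. Over the 77 pairs under 10 kb apart rho was 0.227 (permutation p = 0.0479, adjusted p = 0.188) and Pearson's r was 0.136 (permutation p = 0.233). Without the 2 pairs whose first region lay farthest from the median of the first regions, rho was 0.25 and r 0.166. The rho over all 77 pairs fails the correction for 12 tests. Regions at 0 lying side by side and similar lengths of neighbours could each contribute: without regions at 0 rho was 0.211 (p = 0.0828) and corrected for length it was 0.193 (p = 0.0937), so neither was excluded and neither removed most of the correlation. No biological explanation was tested.

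The excess of regions under 10 kb apart is the pattern that most invites a second look. Uneven density on a scale of 5 Mb or more is argued against, since placements that kept the number of regions in every 5 Mb window still gave fewer pairs, with an observed to expected ratio of 1.59 (one-sided permutation test by placement, p = 0.0002). Windows of 2 Mb and 1 Mb, tried afterwards, gave ratios of 1.59 and 1.57; density that varies at finer scales was not tested and stays open. A broad region split by the peak caller might add pairs at the shortest gaps. Gaps under 2.5 kb had a ratio of 1.47 (95% counting interval 0.871 to 2.32), gaps of 5 to 10 kb had 1.91 (1.40 to 2.55), and the overlapping intervals leave this open. A candidate explanation for the 5 to 10 kb gaps is that the regions are the 2 ends of 1 repeated element, such as the terminal repeats of a retrotransposon; the rho of the paired lengths was -0.13 (p = 0.393) and that of the paired ratios 0.257 (p = 0.0834) over 46 pairs, which neither excludes nor favours it without the sequence.

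For the rise of the ratio with length, regions at 0 are not the whole cause, since rho without them was 0.0655 with a sign-flip permutation p of 0.00586. Counting noise of short regions could contribute. The 1 added to the denominator lowers a ratio most where the denominator is small, but the effect on medians and means was not measured. Longer regions exceeded shorter ones by 0.0730 ± 0.0600 in median ratio (SD, n = 10 chromosomes) and by 0.0397 ± 0.0790 in mean ratio, positive on 9 and 6 of 10 chromosomes. Because the added 1 acts on both, comparing them does not separate this explanation from others, and it stays open.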
